A study of Homo sapiens with 26 samples.

How the data were processed

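The values analysed were fragments per kilobase of gene length, scaled by 1 factor per library (FPKM), for 58735 human genes in 26 libraries, used as deposited. Per the submitters' processing notes, reads were cleaned with fastp, aligned to GRCh38 with HISAT2 version 2.0.5 and counted with featureCounts version 1.5.0-p3, and DESeq2 was named as the tool for differential expression. Per the labels, RNA was selected by poly-A tails and read from directional dUTP libraries. Gene names and coordinates were those that the deposited table gives. All 58735 gene IDs were found in GENCODE release 29 (Ensembl release 94), 58724 with the same coordinates and 58708 with the same name. The FPKM values of each library were turned back into reads through gene length and a factor per library. The recovered values were whole numbers to within 0.01 for 100% of genes, which gave the depth of each library and the counts for 1 alternative. The recovered reads were 0.919 to 1.10 times the number that each library had been scaled to, and above it in 7 libraries, so that number was not the count of mapped fragments. The median-ratio factors of the deposited values lay between 1.011 and 1.017 in all libraries, so the values were already close to a median-ratio scale.

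Genes with an FPKM of 1 or more in at least 3 libraries were tested, 14835 in all. Their log2(FPKM + 1) values were fitted with limma version 3.58.1 in R version 4.3.3, with 1 mean for each cell line and class (12 means, 14 residual degrees of freedom), an intensity trend and moderated variances (prior degrees of freedom 3.84). Every comparison was a contrast of those means. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 14835 genes of each contrast, with a threshold of 0.05. The mean of the 3 lines gave each line equal weight. The replicates are clones, so the p values measure the spread between clones of the same class. The single small CAL51 clone was assumed to vary like the clones of the other groups. Parental libraries were used only against the 2N clones and in the chromosome reference. Small and large 4N clones were each compared with the same 2N clones, so no overlap of those comparisons was interpreted.

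Genes were named by a rule fixed before the data were examined, among protein-coding genes with a symbol and a mean FPKM of 1 or more. For the mean of the 3 lines, the rule took the 12 highest and 12 lowest log2 differences past the threshold with the same sign in each line. Within HCT116 and within DLD1 it took the 10 highest and 10 lowest with no overlap between large and small clones, and within CAL51 the 5 highest and 5 lowest. Where no gene passed, the 5 highest and 5 lowest by the moderated statistic were named as not past the threshold. For each gene list past its threshold, up to 4 members in order of adjusted p could be named, and further members where the list held a member past the threshold. Of the genes the rule chose in DLD1, 2 lie on chromosome Y and are not described. Genes named outside the rule are stated as chosen after their values were seen.

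Gene lists written before the data were examined covered the cell cycle, chromosome structure, the nucleus, protein synthesis and turnover, metabolism, the cytoskeleton, adhesion, differentiation, signalling, stress and immunity. Of 40 lists, 39 had at least 5 tested genes. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Beside each result stands the adjusted p of camera with a correlation estimated from the data. The fry test of limma was a further alternative, and its counts stand beside those of camera.

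For chromosomes, each 4N clone's log2(FPKM + 1) was compared with the mean of its line's 3 2N libraries, over genes with a mean FPKM of 5 or more in the line. The median of each chromosome with at least 50 such genes was taken relative to the clone's median over all genes, and a median of at least 0.2 in size was listed as a shift. The spread of a clone was the standard deviation (SD) of its medians over the 22 autosomes. Large and small clones were compared by an exact permutation test within lines over 2800 arrangements. This part, the recovery of reads and the figures used Python version 3.11.15 with numpy version 2.4.6, pandas version 2.3.3, scipy version 1.17.1 and matplotlib version 3.10.9.

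The procedure was tested on simulated data with known changes. Of 100 genes changed by a log2 of 1, the mean-of-lines contrast recovered 95, HCT116 82, DLD1 81 and CAL51 50. Of 100 genes changed by a log2 of 2, it recovered 100, 98, 98 and 88 in that order. Among the unchanged genes of the 14550 run, between 8 and 12 were called per contrast. Of 10 simulated chromosome shifts of -0.4, 10 were listed, with 0 of 381 other pairs. Camera passed the 1 list that had been shifted by 0.5 and 0 of the other 38. The simulated genes varied independently of each other and no clone was made to stand apart, so the false calls of real clones can be more. Each gene had the same spread in every line. The changed genes were drawn from those expressed in each line and changed equally in all 3. Of the 59 real genes called over the 3 lines, 25 reached a mean FPKM of 1 in all 3, so recovery of genes like the others was not tested. Nor was that of chromosome shifts smaller than 0.4, which all listed real ones were except chromosome 15 in HCT116 small clone 3. Other splits of the real 4N clones within lines gave a median of 41 genes and 14 lists over the 3 lines.

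The alternatives chosen before the data were examined were a log2 difference of at least 1, a pseudocount of 0.1, no filter, protein-coding genes alone, median-ratio and quantile scaling, limma voom on the recovered reads, robust moderation, a replicate block, parental libraries counted with the 2N clones, an additive model, each line left out or fitted alone, each clone left out, and other chromosome measures. Chosen after seeing the data were a filter of mean FPKM 1 in each line, the removal of a trend in GC content and transcript length, scaling to the reads assigned in each library, and 2 more tests of differences between lines. Levels of chromosome Y genes and of XIST are not described. Raw reads were not used here.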

Results

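Messenger RNA was sequenced from 26 libraries of 3 established human cancer cell lines, CAL51 from a breast tumour and HCT116 and DLD1 from colorectal tumours. The study made tetraploid (4N) cells by blocking cell division for 20 hr, with 75 µM of the myosin inhibitor blebbistatin in HCT116 and CAL51 or 1.5 µg/mL of the actin inhibitor dihydrocytochalasin B in DLD1. Single cells were grown into clones after 48 hr of recovery, and the 4N clones were sorted by the study into small and large according to cell and nuclear size. HCT116 had 1 parental library, 2 diploid (2N) clones, 3 small and 3 large 4N clones. DLD1 had 1 parental library, 2 2N clones, 3 small and 4 large clones, and CAL51 had 1 parental library, 2 2N clones, 1 small and 3 large clones. Reads assigned to genes ranged from 23.5 M to 44.5 M per library, with a median of 32.5 M. A single read in a gene of 1 kb corresponded to 0.0246 to 0.0400 FPKM, and these floors cover counting error alone. Mitochondrial genes took between 2.42% of reads in DLD1 large clone 4 and 10.1% in HCT116 2N clone 1. Cell line separated the libraries along the first and second principal components (45.5% and 36.2% of the variance). Positions are in GRCh38.

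Large and small 4N clones were compared first over the 3 lines together, to ask what goes with cell size at equal ploidy. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230), which encodes a transcription factor that growth signals switch on within minutes, fell in the large clones by a log2 of 1.41 ± 0.22 (SE, 10 large and 7 small clones, adjusted p = 0.00812). Its FPKM in HCT116 was 141 ± 42.8 (SD, n = 2) in 2N clones, 54.95 ± 27.6 (n = 3) in small clones and 19.1 ± 0.154 (n = 3) in large clones. In DLD1 the 2N clones had 10.4 ± 0.896 (n = 2), the small clones 22.4 ± 5.86 (n = 3) and the large clones 11.7 ± 2.24 (n = 4). In CAL51 the FOS difference rests on 1 small clone. Its log2 there ran from -2.312 to -1.684 with each large clone left out in turn. NOXA1, an activator of an enzyme that makes superoxide, fell by 0.89 ± 0.13 (adjusted p = 0.00467). CD47, the surface signal that restrains engulfment by macrophages, fell by 1.08 ± 0.21 (adjusted p = 0.031). PLAGL1, an imprinted zinc finger gene, rose by 1.15 ± 0.19 (adjusted p = 0.00974), and the membrane protein gene FAM171A1 rose by 1.55 ± 0.28 (adjusted p = 0.0203). IFT57, part of the machinery that carries cargo along cilia, fell by 0.55 ± 0.10 (adjusted p = 0.0203), and its log2 differences in HCT116, DLD1 and CAL51 were -0.41, -0.57 and -0.66.

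In that comparison 59 genes passed, 28 higher and 31 lower in large clones, and 24 of them had the same sign in each line. Other splits of the same clones within lines gave up to 410 genes, so chance could not be excluded for the count. Of the 22 named genes past the threshold, 8 also passed with each clone but the single small CAL51 clone left out in turn, and FOS, NOXA1 and PLAGL1 were among them. That small clone could not be left out, although it alone sets the small mean of its line. Of the same 22 genes, 6 passed with limma voom on recovered reads, 2 with the additive model, 5 without CAL51, 1 without DLD1 and 9 without HCT116. In CAL51, 2N clone 1 resembled the small clone at PLAGL1 (0.0732 and 0.0516 FPKM, against 2.40 to 5.70 in the other CAL51 libraries) at CD47 (24.5 and 28.4 FPKM, against 5.72 to 8.57) and at IFT57 (25.1 and 23.5 FPKM, against 12.4 to 16.7), so there the difference does not follow size alone. Adjusted p reached 0.0701 for CD47 without DLD1 small clone 3, 0.0523 for FAM171A1 without HCT116 large clone 1 and 0.0527 for IFT57 without DLD1 small clone 3. The count itself was 25 without DLD1 small clone 3, 26 without HCT116 large clone 1, 32 without either DLD1 large clone 3 or HCT116 small clone 1, 33 without DLD1 large clone 4 and 38 without DLD1 small clone 2. It was 150, 101 and 130 without CAL51 large clone 1, 2 and 3. The pooled spread per gene is small for genes silent in some lines, and 21 of the 59 genes reached a mean FPKM of 1 in only 1 line. With a filter of mean FPKM 1 in each line, chosen after seeing the data, 6 genes passed.

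As groups, the nuclear genes for oxidative phosphorylation stood higher in large clones, with a median log2 difference of 0.14 and 44 of 46 members higher (camera adjusted p = 1.7e-06, adjusted p = 0.821 with an estimated correlation). NF-kB, cytokine and secretory genes had a median of 0.41 (camera adjusted p = 6.55e-05, adjusted p = 0.367 with an estimated correlation). Cohesin and condensin genes, which hold and compact chromosomes, had a median of -0.14 with 20 of 24 lower (camera adjusted p = 0.000391, adjusted p = 0.627 with an estimated correlation). Genes of the nuclear lamina and envelope, the shell of the nucleus, had a median of -0.10 (camera adjusted p = 0.0457, adjusted p = 0.367 with an estimated correlation). SYNE2, which links that shell to the cytoskeleton, was the 1 member past the threshold adjusted over the list alone, with a log2 difference of -0.47 ± 0.13, and 0 members passed over all genes. Mesenchymal genes had a median of 0.27 (camera adjusted p = 0.00261, adjusted p = 0.367 with an estimated correlation), with 4 members past adjusted over the list alone and 1 over all genes, CDH2. CDH2 reached a mean FPKM of 1 in CAL51 alone, where the comparison rests on 1 small clone. YAP and TAZ targets, which respond to cell shape and tension, had a median of 0.19 (camera adjusted p = 0.0188, adjusted p = 0.737 with an estimated correlation). In all, 11 of 39 lists passed, and 0 did with an estimated correlation. Without CAL51 large clone 1, 7 lists passed, without CAL51 4 of the 11 were kept, and without HCT116 17 passed, 9 of the 11 among them. With the fry test of limma, 0 lists passed for large versus small clones over the 3 lines, 1 in HCT116, 1 in DLD1 and 2 in CAL51, and 0 passed in each of the 3 comparisons with 2N clones.

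Within HCT116, CAV1 (ENSG00000105974, chromosome 7, 116524785 to 116561184) encodes caveolin, the coat of small membrane pits, and rose by 2.24 ± 0.36 (SE, 3 large and 3 small clones, adjusted p = 0.0085). Its FPKM was 31.9 ± 16.5 (SD, n = 3) in small clones, 142 ± 37.5 (n = 3) in large clones and 115 ± 31.3 (n = 2) in 2N clones. F3, tissue factor, which starts blood clotting, rose from 6.93 ± 3.6 to 44.3 ± 27.4 FPKM (log2 difference 2.46 ± 0.45, adjusted p = 0.0197), and GALNT5, an enzyme that adds sugars to secreted proteins, from 3.06 ± 0.658 to 28.6 ± 13.5 FPKM (2.79 ± 0.46, adjusted p = 0.0085). SAT1 (ENSG00000130066, chromosome X, 23783173 to 23786226), which breaks down polyamines, fell from 228 ± 47.0 to 61.5 ± 35.6 FPKM, against 309 ± 39.5 in 2N clones (log2 difference -2.002 ± 0.316, adjusted p = 0.00779). ATP2A3, a calcium pump of the endoplasmic reticulum, fell by 0.75 ± 0.12 (adjusted p = 0.00779), and NR4A2, a nuclear receptor induced by stimulation, fell by 1.61 ± 0.29 (adjusted p = 0.0197).

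Among the HCT116 genes, 66 passed, 44 higher and 22 lower in large clones. CAV1, SAT1, ATP2A3 and the keratin gene KRT6A were the 4 of 22 named genes that also passed with each clone left out in turn. Without HCT116 small clone 1 the adjusted p was 0.114 for F3 and 0.113 for NR4A2, and without HCT116 large clone 1 it was 0.0519 for GALNT5. The count was 1035 without HCT116 large clone 2, 154 and 139 without small clones 2 and 3, 29 without small clone 1 and 28 without large clone 1. The other splits of the 6 clones, too few to give a share under 0.05, gave up to 203 genes. Of the 22 named genes, 1 passed when HCT116 was fitted alone. Only 3 genes passed when HCT116 was fitted alone, without the spread shared with the other lines. A mean FPKM of 1 was reached in only 1 line by 20 of the 66 genes.

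Ribosome biogenesis genes, which build ribosomes in the nucleolus, stood higher in large HCT116 clones, with a median of 0.61 and 41 of 42 members higher (camera adjusted p = 3.2e-20, adjusted p = 0.455 with an estimated correlation). Of them, 32 passed adjusted over the list alone and 0 over all genes, where BOP1, needed for the large ribosomal subunit, had 1.04 ± 0.24 (adjusted p = 0.0615). The mean list level, in log2(FPKM + 1), was 5.07, 4.67 and 5.58 in large clones 1 to 3 and 4.30, 4.54 and 4.76 in small clones 1 to 3, against 4.61 to 4.69 in the 2N libraries. Without large clone 3 the list median was 0.37. DNA replication genes had a median of 0.33 (camera adjusted p = 3.27e-08, adjusted p = 0.778 with an estimated correlation), with 1 member past adjusted over the list alone and 0 over all genes. Nuclear pore genes had 0.25 (camera adjusted p = 7.55e-07, adjusted p = 0.455 with an estimated correlation), and nuclear transport receptors 0.27 (camera adjusted p = 4.66e-05, adjusted p = 0.455 with an estimated correlation). YAP and TAZ targets had 0.40 (camera adjusted p = 0.00021, adjusted p = 0.455 with an estimated correlation), with 5 members past adjusted over the list alone and 1 over all genes, F3. Immediate early and MAPK feedback genes had -0.44 (camera adjusted p = 0.00143, adjusted p = 0.778 with an estimated correlation), with 8 members lower and 3 higher adjusted over the list alone and 0 over all genes. Histone genes had -0.45 with 14 of 15 lower (camera adjusted p = 0.00173, adjusted p = 0.199 with an estimated correlation). The 12 lists past the threshold also held chaperones, homologous recombination, ribosomal proteins, proteasome and actin, and 0 of the 12 passed with an estimated correlation.

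In DLD1, the clearest change was in an intestinal gene. VIL1 (ENSG00000127831, chromosome 2, 218419092 to 218453295), the actin bundler of the gut brush border, was at 7.48 ± 2.0 FPKM (SD, n = 3) in small clones and fell to 0.305 ± 0.132 (n = 4) in large clones, a log2 difference of -2.68 ± 0.14 (adjusted p = 3.62e-09). The 2N clones had 0.589 ± 0.308 (n = 2). HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188), which shows peptides to T cells, rose from 1.67 ± 0.547 in small to 11.02 ± 3.75 FPKM in large clones (2.14 ± 0.22, adjusted p = 5.99e-05), and the 2N clones had 9.45 ± 0.414. GJA3, a gap junction protein, rose from 0.369 ± 0.126 to 3.89 ± 1.12 FPKM (1.81 ± 0.19, adjusted p = 6.82e-05). CRTAM, an adhesion molecule known from T cells, rose by 1.80 ± 0.21 (adjusted p = 0.000273), and QPCT, which caps the ends of secreted peptides, by 1.44 ± 0.18 (adjusted p = 0.000308). MYO15B, a myosin-related gene, fell by 1.81 ± 0.22 (adjusted p = 0.000308). CTNNA1 (ENSG00000044115, chromosome 5, 138610967 to 138935034), the alpha-catenin that ties cell junctions to actin, was at 23.4, 2.59 and 2.24 FPKM in small clones 1 to 3 and at 36.4 ± 2.61 (n = 4) in large clones (2.51 ± 0.44, adjusted p = 0.00929).

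Of the DLD1 genes, 70 passed, 21 higher and 49 lower in large clones. VIL1, HLA-B, GJA3, CRTAM, QPCT and MYO15B were among the 8 of 18 named genes that also passed with each clone left out in turn. CTNNA1 had an adjusted p of 0.0926 without DLD1 small clone 3. At 65 of the 70 genes the small clones' mean lay farther from the 2N clones' mean than the large clones' mean did, against 57.8% of all tested genes. In HCT116 the small clones were farther at 13.6% of the 66 genes, against 34.5% of all tested genes, and in CAL51 the small clone was farther at 59.3% of the 226, against 51.1% of all. The other splits of the 7 clones gave up to 25 genes. The count was 31 without small clone 3, 36 without large clone 3 and 44 without large clone 4, and 18 with DLD1 fitted alone, 3 of the 18 named genes among them. A mean FPKM of 1 was reached in only 1 line by 28 of the 70 genes.

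Intestinal differentiation genes stood lower in large DLD1 clones, with a median of -0.23 and 11 of 15 lower (camera adjusted p = 0.00431, adjusted p = 0.324 with an estimated correlation). VIL1 passed over all genes, and VIL1 and the secreted trefoil gene TFF1 passed adjusted over the list alone, 2 members in all. Ribosomal protein genes had a median of 0.11 with 69 of 75 higher (camera adjusted p = 0.0011, adjusted p = 0.931 with an estimated correlation). NRF2 targets, which guard against oxidants, had -0.14 (camera adjusted p = 0.017, adjusted p = 0.931 with an estimated correlation), and mitochondrially encoded mRNAs had -0.24 (camera adjusted p = 0.017, adjusted p = 0.931 with an estimated correlation). Glycolysis and hypoxia genes had 0.12 (camera adjusted p = 0.0435, adjusted p = 0.931 with an estimated correlation). These were the 5 lists past the threshold, and 0 passed with an estimated correlation. Without either DLD1 small clone 3 or large clone 4, 3 lists passed.

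In CAL51, 3 large clones were compared with a single small clone. GPC3, a cell surface proteoglycan, was at 23.6 FPKM in the small clone and rose to 316 ± 43.4 (SD, n = 3) in large clones, a log2 difference of 3.68 ± 0.32 (adjusted p = 7.02e-06), and the 2N clones had 156 ± 89.0 (n = 2). CDH2, the N-cadherin of mesenchymal cells, rose by 2.27 ± 0.26 (adjusted p = 0.000137), and WLS, which carries WNT proteins out of the cell, by 3.44 ± 0.45 (adjusted p = 0.000457). SOST, a secreted WNT inhibitor, rose by 4.54 ± 1.01 (adjusted p = 0.0276). MMP28, a secreted protease, fell from 35.1 to 0.227 ± 0.268 FPKM (-4.90 ± 0.56, adjusted p = 0.000124), and KRT19, an epithelial keratin, fell from 93.7 to 6.84 ± 4.49 (-3.79 ± 0.51, adjusted p = 0.00058). CD44 (chromosome 11, 35138870 to 35232402), the hyaluronan receptor, fell from 62.0 to 2.91 ± 1.91 FPKM (-4.15 ± 0.93, adjusted p = 0.0297). CD44 also differed between the 2N clones, at 41.9 FPKM in 2N clone 1 and 3.59 in 2N clone 2.

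Of the CAL51 genes, 226 passed, 109 higher and 117 lower in large clones, and 19 of 27 named genes also passed with each large clone left out. CD44 had an adjusted p of 0.052 without large clone 3. The small clone could not be left out, so the state of that clone and its size class cannot be separated. Part of that state was shared with 2N clone 1, the library nearest to it, with an SD of 0.336 for the log2 differences between the pair, against 0.488 to 0.692 between the small clone and the other CAL51 libraries. The count was 428 without large clone 1 and 367 without large clone 3, and 2 with CAL51 fitted alone, with 0 of the 27 named genes past. A mean FPKM of 1 was reached in only 1 line by 87 of the 226 genes.

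Ribosome biogenesis genes stood lower in large CAL51 clones, with a median of -0.34 and 41 of 42 members lower (camera adjusted p = 6.46e-05, adjusted p = 0.704 with an estimated correlation). The mean list level was 5.14 in the small clone and 5 in 2N clone 1, against 4.68 and 4.69 in the other 2N libraries and 4.69 to 4.94 in the large clones. Oxidative phosphorylation genes had a median of 0.28 with 46 of 46 higher (camera adjusted p = 3.94e-05, adjusted p = 0.704 with an estimated correlation). NF-kB, cytokine and secretory genes had 0.75 (camera adjusted p = 0.000601, adjusted p = 0.503 with an estimated correlation). Mesenchymal genes had 0.75 (camera adjusted p = 0.0018, adjusted p = 0.441 with an estimated correlation), with CDH2, the collagen cross-linker LOX and the growth factor receptor PDGFRB, 3 members, past both over all genes and adjusted over the list alone, though PDGFRB had an adjusted p of 0.0589 without CAL51 large clone 3. Nuclear lamina and envelope genes had -0.25 with 20 of 24 lower (camera adjusted p = 0.00468, adjusted p = 0.296 with an estimated correlation). Targets of p53, the damage-sensing transcription factor, had 0.34 with 28 of 32 higher (camera adjusted p = 0.00233, adjusted p = 0.702 with an estimated correlation). Antigen presentation genes had 0.33 (camera adjusted p = 0.00409, adjusted p = 0.533 with an estimated correlation). In all, 19 lists passed, 8 higher and 11 lower, and 0 of the 19 passed with an estimated correlation.

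**Figure D1:**
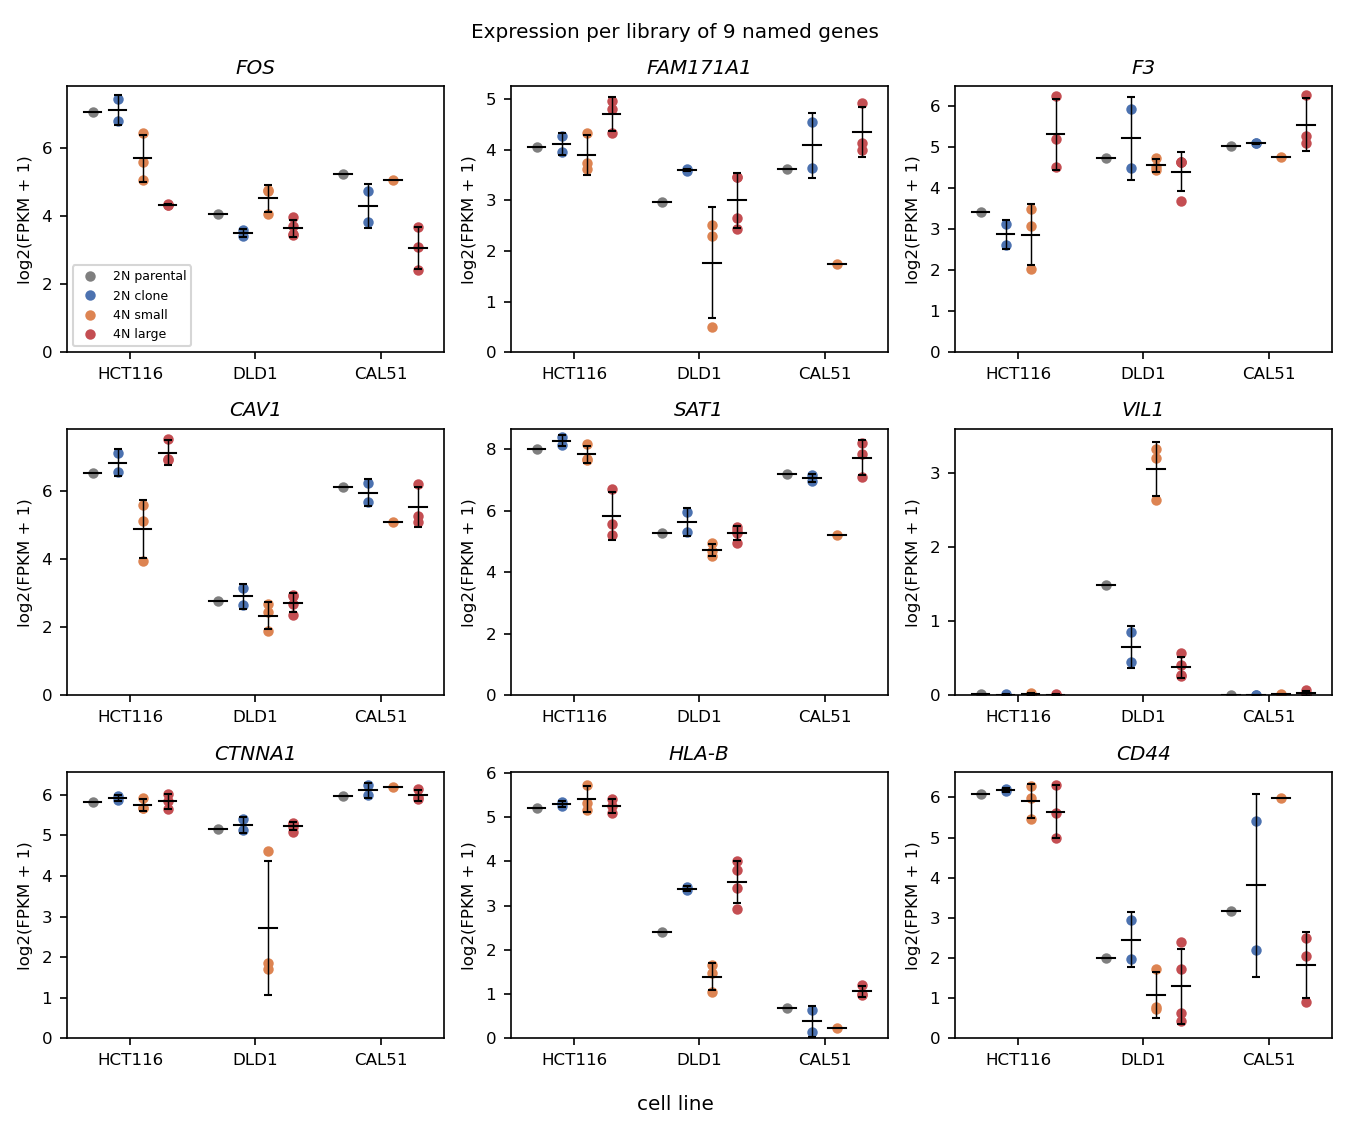
Expression of 9 named genes in log2(FPKM + 1), each point 1 library, by cell line and class, with the mean as a line and the SD as bars. VIL1 was at 7.48 FPKM on average in small DLD1 clones and 0.305 in large DLD1 clones, and SAT1 went from 228 in small to 61.5 in large HCT116 clones.

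**Figure D2:**
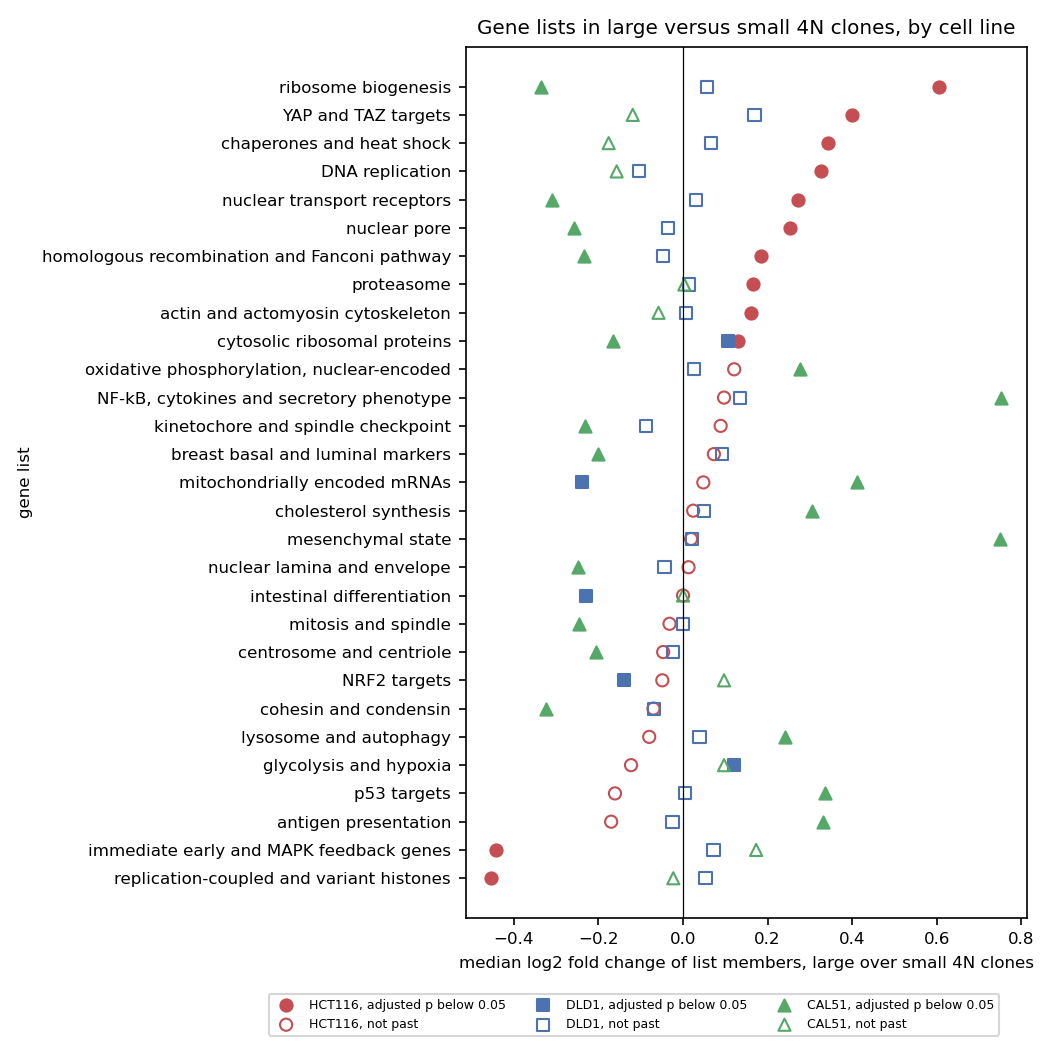
Median log2 difference of list members between large and small 4N clones, by cell line, with filled marks where the camera adjusted p was below 0.05. Ribosome biogenesis genes lay at 0.61 in HCT116 and -0.34 in CAL51.

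Whether the lines differed was tested directly. The large and small clones of DLD1 were made with dihydrocytochalasin B, and those of HCT116 and CAL51 with blebbistatin. Line and drug therefore cannot be told apart wherever DLD1 is compared with another line. Between HCT116 and DLD1, VIL1 differed in its size effect by a log2 of 2.67 ± 0.20 (adjusted p = 2.12e-06), HLA-B by -2.30 ± 0.32 (adjusted p = 0.00312) and SAT1 by -2.56 ± 0.43 (adjusted p = 0.0192). VIL1 reached a mean FPKM of 1 in DLD1 alone, so its difference is the change within DLD1. SAT1 rose in large CAL51 clones by 2.52 ± 0.45 (adjusted p = 0.00597), and its HCT116 minus CAL51 difference, a test chosen after seeing the data, was -4.52 ± 0.55 (adjusted p = 0.000409). That opposite direction rests on the single small CAL51 clone, at 35.7 FPKM, since the 2N and parental CAL51 libraries had 125 to 144 and the large clones 136 to 295. For CAV1, F3 and CTNNA1 the HCT116 minus DLD1 difference had adjusted p values of 0.219, 0.142 and 0.201. In all, 23 genes differed between HCT116 and DLD1, 15 with a higher difference in HCT116 and 8 lower. A mean FPKM of 1 was reached in only 1 line by 12 of these 23 genes, in 2 lines by 3, in all 3 lines by 5 and in no line by 3. The count of 23 was 97 without HCT116 large clone 2, 50 without DLD1 small clone 1 and 12 without either HCT116 small clone 1 or DLD1 small clone 3. Ribosome biogenesis genes differed by a median of 0.56 between HCT116 and DLD1 (camera adjusted p = 2.04e-12, adjusted p = 0.714 with an estimated correlation) and by 0.97 between HCT116 and CAL51 (camera adjusted p = 1.88e-15, adjusted p = 0.475 with an estimated correlation). Replication-coupled and variant histone genes differed by -0.69 between HCT116 and DLD1 (camera adjusted p = 0.000188), which held with an estimated correlation (adjusted p = 0.0482), as the 1 of 12 lists that did. No list passed with an estimated correlation in any other contrast tested. RNA was selected by poly-A tails, so any histone transcripts without such tails would be missed or undercounted. No gene passed in the same direction in any 2 lines, where 0.062 to 0.386 shared genes per direction would be drawn by chance.

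Across the 14835 genes, which are not independent replicates, the log2 differences of HCT116 and DLD1 had a Spearman correlation of 0.111 (Pearson 0.105). Splits of the 4N clones into groups of the same sizes gave -0.129 to 0.126. For HCT116 and CAL51 it was -0.243 (Pearson -0.181), and the splits ranged from -0.204 to 0.243. DLD1 and CAL51 had 0.00 (Pearson 0.009), with splits from -0.110 to 0.0760.

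The series title ties cell size to chromosomal instability, and a chromosome gained or lost throughout a clone moves the median of its genes. Each library is of a whole clone, so differences between the cells of a clone were not measured. The medians therefore do not measure a rate of gains and losses. A loss of 1 of 4 copies would give a log2 of -0.42 and a gain to 5 of 4 copies 0.32, if expression followed dose. Chromosome 15 was lowest in HCT116 small clone 3, at -0.45, with 95.7% of its 187 genes on that side, but the reference was uneven there, with HCT116 2N clone 2 itself at 0.378, and the shift was 0.315 in size against the nearest 2N library. DLD1 large clones 2 and 4 both had a lower chromosome 7, at -0.30 and -0.29. DLD1 large clone 2 also had chromosome 10 at -0.33, and DLD1 large clone 1 had chromosome 3 at -0.28 over 376 genes. CAL51 large clone 2 had chromosome 10 at 0.25 and chromosome 11 at 0.28. HCT116 large clone 1 had chromosome 1 at -0.30, and HCT116 large clone 3 had chromosome 5 at 0.28. In DLD1 small clone 1, chromosome 5 was at -0.29, from -0.32 to -0.36 in 3 of 4 blocks of its genes and 0.06 in the first. CAL51 large clone 1 had chromosomes 13, 18 and 19 at -0.32, -0.24 and 0.27, and 0 of these 3 stayed at 0.2 or beyond when a trend in GC content and length was removed.

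Of 391 clone and chromosome pairs, 17 had a shift, in 12 of 17 clones. Small clones had 5 shifts in 5 of 7 clones, all 5 lower, and 1 of them, chromosome 15 in HCT116 small clone 2 at -0.23, came to only 0.092 in size against 1 of the 2N libraries. Large clones had 12 shifts in 7 of 10 clones, 5 higher and 7 lower. The SD of chromosome medians was 0.068 ± 0.036 (SD, n = 4) in large and 0.054 ± 0.029 (n = 3) in small DLD1 clones, against 0.030 ± 0.002 (n = 2) in 2N clones and 0.018 in the parental library. In HCT116 it was 0.077 ± 0.026 (n = 3) in large and 0.068 ± 0.038 (n = 3) in small clones, against 0.063 ± 0.029 (n = 2) in 2N clones and 0.043 in the parental library. In CAL51 it was 0.087 ± 0.056 (n = 3) in large clones, 0.056 in the small clone, 0.025 ± 0.008 (n = 2) in 2N clones and 0.024 in the parental library. Over the 3 lines the large clones exceeded the small ones by 0.018, which the two-sided exact permutation test within lines did not separate from 0 (p = 0.468, smallest possible p 0.000357). The difference was 0.009 without CAL51 large clone 1 and 0.028 without CAL51 large clone 3. The 2N libraries set the reference and had shifts of their own, such as chromosome 15 at 0.38 in HCT116 2N clone 2, so their spread is not directly comparable.

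**Figure D3:**
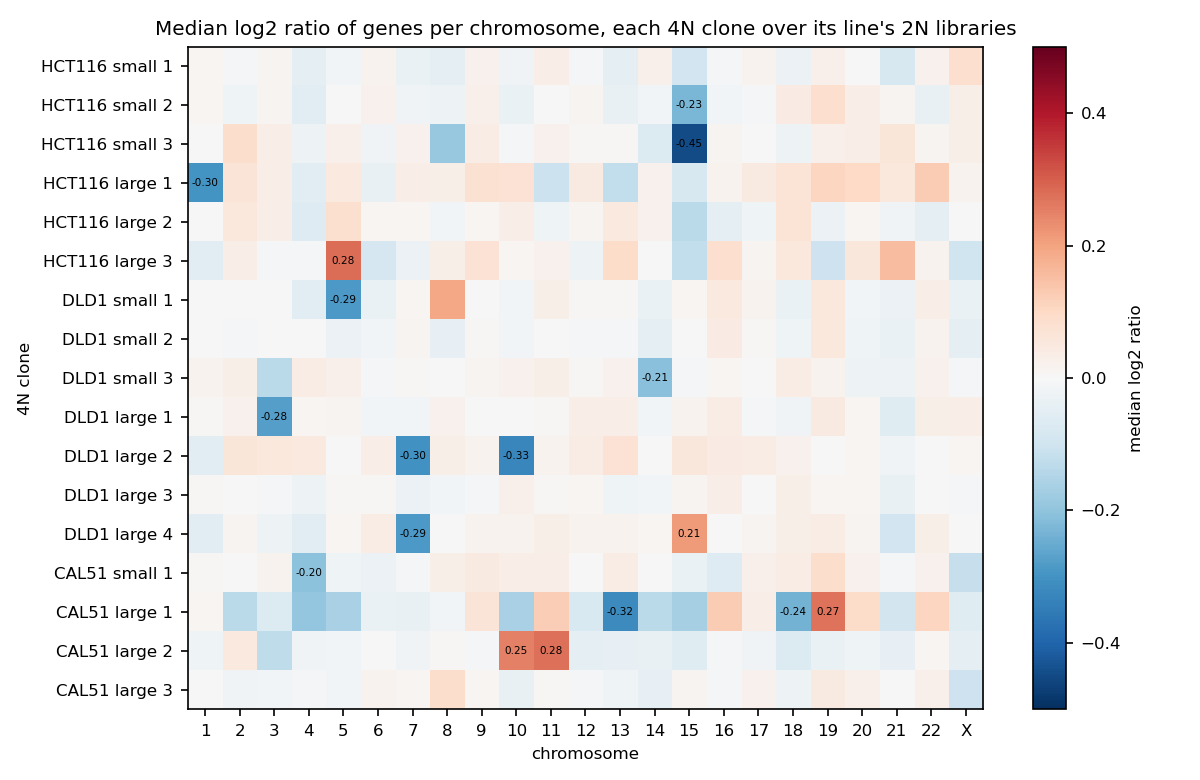
Median log2 difference of the genes of each chromosome from the line's 2N libraries, for the 17 4N clones, with values of 0.2 or more in size written in. Chromosome 15 in HCT116 small clone 3 had the lowest median, -0.45.

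For ploidy, all 4N clones were set against the 2N clones. The labels give a drug block of cell division and a recovery for the 4N clones only. Ploidy therefore cannot be told apart from that treatment and from survival after it, in any comparison of 4N with 2N clones. LEFTY1, an inhibitor of NODAL signalling chosen after its values were seen, fell by 0.81 ± 0.10 (SE, 17 4N and 6 2N clones, adjusted p = 0.00398) and was the 1 gene past the threshold among 742 with an unadjusted p below 0.05. LEFTY1 reached a mean FPKM of 1 in 1 line alone, and its log2 differences in HCT116, DLD1 and CAL51 were -0.005, 0.003 and -2.44. Its call was lost with parental libraries counted among the 2N clones, with a pseudocount of 0.1, with limma voom, with the additive model and without CAL51 or DLD1. The genes named by rule did not pass. CDH2 had a log2 difference of -0.65 ± 0.11 (adjusted p = 0.0958), SAT1 -0.90 ± 0.19 (adjusted p = 0.319) and LITAF, a gene of endosomal sorting, -0.78 (adjusted p = 0.319), and on the other side ZNF79 had 0.31 ± 0.07 (adjusted p = 0.447) and POLR2A, the main subunit of RNA polymerase II, 0.37 (adjusted p = 0.658). Without CAL51 2N clone 1 the count was 10, without CAL51 2N clone 2 it was 7, and without CAL51 large clones 1, 2 and 3 it was 5, 4 and 5. It was 3 without HCT116 2N clone 1, small clone 1 or large clone 2, and 2 without DLD1 small clone 1. Targets of p53 stood higher in 4N clones, with a median of 0.18 and 29 of 32 higher (camera adjusted p = 9.58e-08, adjusted p = 0.639 with an estimated correlation). Immediate early genes had -0.27 with 23 of 27 lower (camera adjusted p = 6.62e-07, adjusted p = 0.639 with an estimated correlation), and proteasome genes 0.13 with 28 of 29 higher (camera adjusted p = 3.46e-07, adjusted p = 0.696 with an estimated correlation). In all, 17 of 39 lists passed, and 0 did with an estimated correlation. Without HCT116 6 lists passed, 4 of them among the 17, and without DLD1 11 passed.

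Within lines the 4N versus 2N comparison gave a few genes each, all chosen after their values were seen. In HCT116, FOS fell in 4N clones by 2.10 ± 0.34 (6 4N and 2 2N clones, adjusted p = 0.0152) and the WNT inhibitor DKK1 rose by 1.78 (adjusted p = 0.0376). In CAL51, LEFTY1 fell by 2.44 ± 0.19 (4 4N and 2 2N clones, adjusted p = 2.94e-06) and CDH2 by 1.84 ± 0.21 (adjusted p = 0.000496). The contrast weights the size classes equally, so the single small CAL51 clone, at 3.28 FPKM of CDH2, counted as much as the 3 large clones at 13.6 to 31.7, and the parental library was at 9.41. In DLD1, VIL1 had a log2 difference of 1.06 ± 0.15 (7 4N and 2 2N clones, adjusted p = 0.00802). It came from the small clones, at 5.22 to 8.99 FPKM, since the large clones at 0.203 to 0.482 were all below the higher of the 2N clones, at 0.372 and 0.807, and 0 of the 5 DLD1 genes kept their call without either 2N clone. In HCT116 16 genes passed, 5 higher and 11 lower, in DLD1 5 genes, 4 higher and 1 lower, and in CAL51 16 genes, 1 higher and 15 lower. The HCT116 count was 5 without either 2N clone, 63 and 27 without small clones 1 and 2, and 93 and 27 without large clones 2 and 3. The DLD1 count was 2 and 0 without 2N clones 1 and 2, 14, 10 and 3 without small clones 1 to 3, 2 without large clone 1 and 8 without large clone 3. The CAL51 count was 48 and 25 without 2N clones 1 and 2, and 32, 27 and 38 without large clones 1 to 3. Whether the 4N versus 2N changes of FOS, LEFTY1, CDH2 or VIL1 differed between lines was not tested.

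Each size class was also set against the 2N clones over the 3 lines. In small clones VIL1 rose by 0.81 ± 0.11 (SE, 7 small and 6 2N clones, adjusted p = 0.00526), CDH2 fell by 1.04 ± 0.14 (adjusted p = 0.00526) and LITAF fell by 1.22 ± 0.20 (adjusted p = 0.0479), the 3 genes past the threshold. VIL1 and CDH2 each reached a mean FPKM of 1 in 1 line alone, VIL1 in DLD1 and CDH2 in CAL51, so these means over 3 lines are changes within a single line. LITAF was at 2.58 FPKM in the single small CAL51 clone, against 30.6 and 40.6 in the CAL51 2N clones, while its ranges in small HCT116 clones (14.9 to 20.96) and small DLD1 clones (5.36 to 10.8) overlapped those of the 2N clones (17.6 and 19.2, and 9.05 and 12.2). The count of genes was 37 and 5 without CAL51 2N clones 1 and 2, and 8 without DLD1 small clone 1. In large clones FOS fell by 1.29 ± 0.21 (10 large and 6 2N clones, adjusted p = 0.0335), LEFTY1 by 1.27 ± 0.11 (adjusted p = 1.18e-05) and ID4, an inhibitor of differentiation factors, by 0.86 ± 0.11 (adjusted p = 0.00331). IRX6, a homeobox gene, fell by 0.64 and LONRF2, a ubiquitin ligase gene, by 0.45, which made 5 genes, all chosen after their values were seen, of which 3 reached a mean FPKM of 1 in 1 line alone. The FOS call was lost without any 1 of the 6 DLD1 2N and large clones, without HCT116 2N clone 2, large clone 1 or large clone 3, without any 1 of the 3 lines, with limma voom, genes expressed in each line, a pseudocount of 0.1, the additive model, the GC content and length trend removed or values scaled to the reads of each library. In DLD1 the large clones, at 11.7 FPKM, were not below the 2N clones, at 10.4. Leaving out any clone but HCT116 2N clone 1 moved the count by over 1.5 times, to 48, 29 and 18 without CAL51 2N clone 2, CAL51 large clone 3 and CAL51 large clone 1, and to between 2 and 10 without the others. Kinetochore and spindle checkpoint genes, which attach chromosomes for division, stood higher in small than in 2N clones, with a median of 0.11 and 36 of 40 higher (camera adjusted p = 1.43e-05, adjusted p = 0.551 with an estimated correlation). NF-kB, cytokine and secretory genes had -0.26 in small clones (camera adjusted p = 1.43e-05, adjusted p = 0.36 with an estimated correlation). In large clones, oxidative phosphorylation genes had 0.17 with 46 of 46 higher (camera adjusted p = 8.26e-10, adjusted p = 0.772 with an estimated correlation), and immediate early genes -0.27 with FOS past over all genes and 6 members lower and 1 higher adjusted over the list alone (camera adjusted p = 6.17e-07, adjusted p = 0.621 with an estimated correlation). Without DLD1 2N clone 2, 9 lists passed for small versus 2N clones, against 18 with all clones, and without CAL51 large clone 1, 19 passed for large versus 2N clones, against 11. Without CAL51 17 lists passed for large versus 2N clones, and without HCT116 5 did, 3 of them among the 11. Against the parental lines, the 2N clones had 1 gene past the threshold, the small secreted protein gene C4orf48, higher by 1.49 ± 0.19 (6 clones and 3 parental libraries, adjusted p = 0.00465), and without CAL51 2N clone 2 that count was 6.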

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

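The count of genes at which the small DLD1 clones depart from the 2N clones, the removal of the GC content and length trend, the list tests against CAL51, the use of the splits against a pooled spread and the SAT1 test against CAL51 were chosen after the results were seen, and the other tests of this part were chosen before.

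Single libraries stood apart in the group of 4 large DLD1 clones, by a gap to the nearest clone above Dixon's 95% critical share of the group's range. DLD1 large clone 2 did so at MIER1 (6.251 FPKM), LITAF (19.66 FPKM), F3 (12 FPKM) and C1orf116 (3.623 FPKM), which were 4 of 54 named genes tested. DLD1 large clone 4 did so in its number of genes with FPKM of 1 or more, 11508, which was 1 of 10 library measures tested. Chance gives about 1 such gap in 20 independent groups, and these counts are near that share. But the 54 genes were chosen for large changes and share the same 4 libraries, so the share cannot decide whether large clone 2 stands apart. The SD of log2 differences was 0.363 to 0.382 between large clone 2 and the other large DLD1 clones, against 0.245 to 0.323 among those.

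At some genes the size effect differed between lines by a test of the difference itself. Line and the drug that blocked division cannot be told apart for HCT116 minus DLD1. For HCT116 minus DLD1 the log2 difference was 2.674 at VIL1, 1.372 at C9orf152, -2.558 at SAT1, -2.295 at HLA-B, -2.017 at GJA3, -1.802 at CRTAM, -1.886 at LAGE3 and -1.439 at QPCT. VIL1 reached a mean FPKM of 1 in DLD1 alone, so its difference is the change within DLD1. For HCT116 minus CAL51 it was -4.524 at SAT1, which rests on the single small CAL51 clone.

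Lists also differed between lines by camera. Line and drug cannot be told apart in the lists for HCT116 minus DLD1 and for DLD1 minus CAL51. For HCT116 minus DLD1 the medians were 0.406 for DNA replication, 0.126 for kinetochore, 0.244 for homologous recombination and Fanconi, 0.268 for nuclear pore, 0.258 for nuclear transport, 0.561 for ribosome biogenesis, 0.216 for chaperone, 0.335 for epithelial junction and 0.229 for intestinal differentiation genes. They were -0.211 for glycolysis and hypoxia, -0.432 for immediate early and -0.686 for histone genes, and of these 12 lists only the histones held with an estimated correlation (adjusted p = 0.0482). With an estimated correlation none of the 16 lists for HCT116 minus CAL51 passed. For these the medians were 0.453 for DNA replication, 0.216 for mitosis, 0.306 for kinetochore, 0.346 for cohesin and condensin, 0.444 for homologous recombination and Fanconi, 0.484 for nuclear pore, 0.576 for nuclear transport, 0.299 for ribosomal protein, 0.967 for ribosome biogenesis, 0.546 for chaperone and 0.464 for YAP and TAZ target genes. They were -0.469 for p53 target, -0.158 for oxidative phosphorylation, -0.445 for mesenchymal, -0.646 for antigen presentation and -0.291 for lysosome and autophagy genes. With an estimated correlation none of the 17 lists for DLD1 minus CAL51 passed. For these the medians were 0.248 for mitosis, 0.301 for cohesin and condensin, 0.184 for homologous recombination and Fanconi, 0.199 for nuclear lamina, 0.198 for nuclear pore, 0.291 for nuclear transport, 0.281 for ribosomal protein, 0.392 for ribosome biogenesis and 0.316 for chaperone genes. They were -0.384 for p53 target, -0.39 for cholesterol synthesis, -0.245 for oxidative phosphorylation, -0.731 for mitochondrially encoded, -0.617 for mesenchymal, -0.429 for antigen presentation, -0.468 for NF-kB and cytokine, and -0.316 for lysosome and autophagy genes.

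The first pattern weighed is ribosome biogenesis, higher in large clones of HCT116 and lower in large clones of CAL51. A trend in GC content or gene length was argued against as the whole cause, since its removal left list medians of 0.567 of 0.606 in HCT116 and -0.321 of -0.335 in CAL51. Single clones stay open. In HCT116 the levels of large clone 2 (4.672) and small clone 3 (4.763) overlapped, though the median without large clone 3 was still 0.366, and in CAL51 3 of 3 large clones lay within the range of the 2N libraries and the lone small clone (5.14) above it, but 2N clone 1 alone set the top of that range (5, against 4.68 and 4.69) and lay near the small clone. The pattern may therefore reflect the growth state of a few clones rather than size class, and growth rate was not measured here.

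The second pattern is the DLD1 gene set that includes VIL1 and HLA-B. With no difference between the classes, a spread per gene pooled over lines would give as many genes in other splits. Of 35 splits, each with a spread pooled over lines, 1 reached the real 70 genes and the highest other gave 25. That argues against a pooled spread as the whole cause of the DLD1 count. But the spread was estimated anew in each split, and a split that mixes the classes adds their difference to it. How much of the count rests on a pooled spread therefore stays open, and 18 genes passed with DLD1 fitted alone. For the single genes, and for the HCT116 and CAL51 counts, a pooled spread and a real effect cannot be told apart, since the 70 of 70 genes in DLD1, 66 of 66 in HCT116 and 194 of 226 in CAL51 with an unadjusted p under 0.05 in the line alone were chosen on the same libraries. The small clones' mean lay farther from the 2N clones at 65 of the 70 genes. Each small clone lay beyond both 2N clones at 62, against 28.9% of all tested genes, and each large clone at 12, against 14.7%. In HCT116 the large clones did so, at 58 of 66 genes, against 33.2% of all tested genes. A candidate explanation for most of the DLD1 set is a state shared by the small clones that 2N and large clones lack. It does not cover the size of the change at CTNNA1, at 23.4 FPKM in small clone 1, which had a lower chromosome 5, and at 2.59 and 2.24 in small clones 2 and 3. Whether the small clones share an ancestor that already held this state, or size itself brings it, was not tested.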

How the results depend on the processing

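Chosen after seeing the data were the filter of mean FPKM 1 in each line, the GC content and length trend, scaling to the reads of each library, and the tolerance of 0.1 for a moved correlation. Across all alternatives, 11160 results for named genes stayed on their side of the threshold, 565 no longer passed and 81 newly passed. A further 2 changed direction with a call in either fit. The 11160 include named genes that passed in neither fit, whose direction was not compared, so they do not give the share of calls kept. Of the 22 named genes past over 3 lines, 22 kept their call with no filter, 6 with limma voom and 2 with the additive model. Of the gene list results, 2471 stayed, 517 no longer passed and 2 changed direction. Of the counts, correlations and chromosome values, 209 stayed and 156 moved, all 156 of them gene counts. The large minus small difference in the spread of chromosome medians, 0.018, was 0.008 with the GC content and length trend removed, 0.009 without CAL51 large clone 1 and 0.028 without CAL51 large clone 3, and its exact permutation p, 0.198 to 0.768, passed under no alternative. The correlations between lines moved by less than the tolerance. Of the numbers of lists past the threshold, 199 stayed and 27 moved, and of the listed chromosome shifts 62 stayed and 6 fell below the limit. Robust moderation moved no count. Median-ratio scaling moved none either, but it hardly changed the values, since its factors for the deposited values lay between 1.011 and 1.017, so it tests little. Scaling to the reads assigned in each library, where recovered reads were 0.919 to 1.10 times the number scaled to, gave 55 over 3 lines, 75 in HCT116, 69 in DLD1 and 195 in CAL51, and moved 1 count, large versus 2N clones, to 3. The cause was not tested except where stated.

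With a log2 difference of at least 1 required, fewer genes can pass: 11 for large versus small over 3 lines, 32 in HCT116, 0 for 4N versus 2N clones and 2 for large versus 2N clones. With a pseudocount of 0.1, the counts were 37 in HCT116, 0 for 4N versus 2N clones (5 within HCT116, 7 within CAL51), 0 for small and 2 for large versus 2N clones, 4 for 2N clones versus parental and 11 for HCT116 minus DLD1. With no filter on low values, large versus small gave 357 over 3 lines, 155 in HCT116 and 730 in CAL51. For 4N versus 2N clones it gave 215, with 188, 47 and 309 within HCT116, DLD1 and CAL51, and then 252 for small and 95 for large versus 2N clones, 639 for 2N clones versus parental and 41 for HCT116 minus DLD1. Protein-coding genes alone gave 5 for small versus 2N clones, and quantile normalization gave 100 in HCT116.

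With limma voom on recovered reads the counts were 10 over 3 lines, 34 in HCT116 and 101 in CAL51. For 4N versus 2N clones they were 0, with 6, 0 and 4 within HCT116, DLD1 and CAL51, and then 0 for small and 1 for large versus 2N clones, 0 for 2N clones versus parental and 6 for HCT116 minus DLD1. The labels do not say whether clone numbers pair the clones. In HCT116, deviations of same-number clones from their class means correlated at 0.028 to 0.197, against -0.197 to 0.162 for other numbers. In CAL51 they were 0.18 and 0.205 against -0.205 to 0.072, and in DLD1 -0.056 to 0.085 against -0.116 to 0.116. Pairing by number therefore stays open in HCT116 and CAL51, and the main fit left it out. A block for the replicate number gave 108 over 3 lines. For 4N versus 2N clones it gave 5, with 3, 22 and 52 within HCT116, DLD1 and CAL51. It gave 12 for small and 28 for large versus 2N clones and 13 for 2N clones versus parental. Calls kept were 12 of 22 named genes over 3 lines, 10 of 22 in HCT116 and 12 of 18 in DLD1. With that block the CAL51 ribosomal protein list changed direction, to 0.168. With parental libraries counted among the 2N clones, large versus small gave 226 in HCT116 and 113 in DLD1, 4N versus 2N gave 97 in HCT116 and 2 in DLD1, small versus 2N gave 8 and HCT116 minus DLD1 gave 35. An additive model of line and class, which assumes equal effects in each line, gave 3 over 3 lines and 0 for 4N, small and large versus 2N clones and for 2N clones versus parental.

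Restricting to genes expressed in each line, which tests fewer genes, gave 6 over 3 lines, 30 in HCT116, 4 in DLD1 and 71 in CAL51. For 4N versus 2N clones it gave 0, with 1, 0 and 1 within HCT116, DLD1 and CAL51, and then 0 for small and 0 for large versus 2N clones, 2 for 2N clones versus parental and 3 for HCT116 minus DLD1. With the GC content and length trend removed, HCT116 gave 115, small versus 2N clones 5 and large versus 2N clones 3. Each line fitted alone has fewer libraries behind its spread and gave 3 in HCT116, 18 in DLD1 and 2 in CAL51, and for 4N versus 2N clones 1 in HCT116 and 0 in CAL51. Without CAL51, 4N versus 2N clones gave 2 and 2N clones versus parental 0, and KRT19 over the remaining lines changed direction, to 0.117. Without DLD1, large versus small gave 17, 4N versus 2N clones 0, small versus 2N clones 0, large versus 2N clones 11 and 2N clones versus parental 0, and VIL1 changed direction, to 0.001. Without HCT116, 4N versus 2N clones gave 2, small versus 2N clones 14, large versus 2N clones 9 and 2N clones versus parental 7, and the ribosome biogenesis list changed direction, to -0.134. These 3 changes follow from the line left out, which carried the value.

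With each clone left out in turn, large versus small ranged from 25 (without DLD1 small clone 3) to 150 (without CAL51 large clone 1) over 3 lines. It ranged from 28 (without HCT116 large clone 1) to 1035 (without HCT116 large clone 2) in HCT116, from 31 (without DLD1 small clone 3) to 88 (without DLD1 large clone 2) in DLD1 and from 235 (without CAL51 large clone 2) to 428 (without CAL51 large clone 1) in CAL51. HCT116 minus DLD1 ranged from 12 (without DLD1 small clone 3) to 97 (without HCT116 large clone 2). For 4N versus 2N clones the range was 1 to 10 (without CAL51 2N clone 1), with 5 to 93 (without HCT116 large clone 2) in HCT116, 0 (without DLD1 2N clone 2) to 14 (without DLD1 small clone 1) in DLD1 and 25 to 48 (without CAL51 2N clone 1) in CAL51. Small versus 2N clones ranged from 2 to 37 (without CAL51 2N clone 1), large versus 2N clones from 2 to 48 (without CAL51 2N clone 2) and 2N clones versus parental from 1 to 6 (without CAL51 2N clone 2). The single small CAL51 clone and the parental libraries could not be left out.

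Depth ranged from 23.5 M to 44.5 M reads. With 3 reads as the limit that a count of 0 allows, genes listed at 0 in a class have no fold difference given.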

Other observations

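The treatment of CAL51 large clone 1 as a pattern of its own and the removal of the GC content and length trend were chosen after the results were seen, and the other tests of this part were chosen before.

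Lists for WNT targets and intestinal stem cells, DNA sensing by cGAS and STING, extracellular matrix, fatty acids, interferon and mTORC1 did not pass for large versus small clones over the 3 lines, with medians of 0.06, -0.06, 0.03, 0.00, -0.07 and 0.00 and camera adjusted p of 0.264, 0.358, 0.306, 0.807, 0.603 and 0.695. CAL51 2N clone 1 stood near the small clone at genes that fell in large CAL51 clones, with MMP28 at 14.2, PRSS35 at 21.5, PPP1R14A at 16.0 and CD44 at 41.9 FPKM. In DLD1, small clones 2 and 3 had CTNNA1 at 2.59 and 2.24 FPKM while chromosome 5, where CTNNA1 lies, was not listed as shifted in either of them.

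The third pattern weighed is the chromosome-wide shifts, for which DNA copy number was not analysed here. For the 14 shifts outside CAL51 large clone 1, a trend in GC content or gene length is argued against, since 14 of 14 kept their size and sign without it. An uneven 2N reference is argued against as the whole cause for 13 of the 14, which kept a size of 0.15 or more against each 2N library alone. Of these 13, chromosome 4 in CAL51 small clone 1 came to 0.193 in size against the nearest 2N library, below the listing limit of 0.2. Chromosome 14 in DLD1 small clone 3 came to 0.186 and chromosome 15 in DLD1 large clone 4 to 0.195. The exception at 0.15 was chromosome 15 in HCT116 small clone 2, at 0.092 in size against 1 2N library, where HCT116 2N clone 2 stood at 0.378 itself. An uneven reference stays open for it, and HCT116 small clone 3 had 0.315 in size on that chromosome against the nearest 2N library. A change of dose along the whole chromosome is a candidate explanation, since in 13 of 14 each of 4 blocks of genes moved the same way. In CAL51 large clone 1, 0 of 3 shifts were kept once the trend was removed, so those 3 may reflect GC content or length, and with 2 of 3 even along the chromosome a change of dose cannot be told apart from it on 3 chromosomes.

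The 4N and 2N clones of each line were also split in other ways into groups of the same sizes. For large versus small in DLD1, the real split gave 70 genes and the highest of the other 34 gave 25. Thus 1 of 35 splits reached the real count, the smallest share that 35 splits allow. That argues against chance for the DLD1 gene count, though the shares were not adjusted over the comparisons that were split. For HCT116 minus DLD1, 2 of 100 splits reached the real 23, a share under 0.05. But the highest other split gave 28 and the comparison uses the same DLD1 clones, so chance was not excluded for it. In HCT116 the splits were too few to give a share under 0.05, with 66 for the real split and 203 for the highest other (3 of 10 as large), and with 12 and 14 lists (4 of 10). Over the 3 lines chance could not be excluded for large versus small, with a real count of 59 and a highest other of 410 (24 of 100). It could not be excluded for 4N versus 2N clones with 1 and 338 (81 of 100), small versus 2N clones with 3 and 574 (84 of 100), large versus 2N clones with 5 and 353 (49 of 100) or 2N clones versus parental with 1 and 4 (7 of 27). The splits that called several times the real count point to a structure of the clones other than size or ploidy class, such as single clones that differ widely from the rest of their line.

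For the number of lists past the threshold, chance could not be excluded in any comparison with enough splits. The real and highest other numbers were 11 and 22 for large versus small over 3 lines (81 of 100), 12 and 17 for HCT116 minus DLD1 (36 of 100), 5 and 12 in DLD1 (28 of 35), 17 and 23 for 4N versus 2N clones (16 of 100), 18 and 21 for small versus 2N clones (8 of 100) and 11 and 22 for large versus 2N clones (60 of 100).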
